A study of Mus musculus with 8 samples.

How the data were processed

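RNA sequencing libraries of tdTomato-positive mouse brain cells were analysed, 2 each from E13, E15, P12 normoxia and P12 hypoxia. Per the labels, total RNA was extracted with a column kit, 400 pg entered each library, and libraries were prepared with the NEBNext Ultra II kit. Hypoxic and control mothers were exchanged as foster mothers during the exposure. The deposited files hold raw counts per gene, 1 file per library, and the submitters' processing notes name cutadapt, STAR and Subread with the GRCm38 build, without versions or settings. The annotation release, the strand setting and the handling of reads that map to several places are not stated, so reads shared between genes and their pseudogenes cannot be resolved. Replicate numbers follow the sample titles, and the numbers written on the P12 files differ from them, so equal numbers name no pair. Deviations from the group mean did not correlate between libraries of equal number (-0.039 to 0.008 over 6 pairs of groups), and no pairing entered the tests.

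Each file held 55487 rows. Of these, 1980 named no gene and held 0.205% to 0.266% of the counts, and they were left out of the tests. A further 14 rows bore dates in place of gene symbols, as a spreadsheet makes them, and were kept but not named. Of the 53507 gene rows 51694 (96.6%) matched a symbol of the GENCODE M21 annotation on GRCm38, from which the coordinates were taken. There were 0 rows for tdTomato or its cassette, so the reporter itself was not measured. Totals per library were 36252027 to 47084796 counts in gene rows, and 3 counts, the limit that a count of 0 allows, correspond to 0.0637 to 0.0828 CPM before scaling. These limits and the 95% counting intervals given with ratios cover counting error only, since reads without molecular identifiers are not independent molecules.

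Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Library sizes were scaled by TMM, and filterByExpr (minimum count 10, minimum total 15) kept 19936 genes. A quasi-likelihood fit of the 4 groups over all 8 libraries (glmQLFit, glmQLFTest, 4 residual degrees of freedom) tested hypoxia against normoxia at P12, E15 against E13, normoxic P12 against the mean of E13 and E15, and both P12 groups against the embryonic groups. All tests were two-sided. The SE given with a log2 fold change was computed from the F statistic of that fit, so it rests on the spread shared by all 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Values per library are CPM, the counts per mega-count of normalised library size, and the per-library mean of a list is of log2(CPM + 1).

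Gene lists, 36 in all, were tested with camera (preset correlation 0.01) against all other genes, Benjamini-Hochberg adjusted over the lists within a comparison, where at least 3 members passed the filter. camera with an estimated correlation and fry were the alternatives. Sets of 500 genes from the contrast of P12 with embryonic cells (log2 fold change of at least 1), and sets of 200 from E15 against E13, were tested with camera in hypoxia against normoxia. The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, up to 8 genes with the largest fold change in each direction among called genes with at least 10 CPM in the higher group and no overlap between sides, or the 4 of smallest p where fewer pass. It adds up to 4 members of smallest p from each list that passed or held at least 2 called genes. For hypoxia against normoxia it adds Mettl14, Mettl3, Ctnnb1, Axin2, Lef1, Eomes, Neurog2, Pax6, Mki67, Vegfa and Slc2a1. Provisional, sex-linked and immunoglobulin genes are skipped, and not every gene so chosen is described, some being withheld and not reported here.

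Alternatives were DESeq2, limma-voom with sample quality weights, relative log expression and upper-quartile scaling, no low-count filter or at least 5 CPM in 2 libraries, a block for the replicate number, only the libraries of the compared groups, removal of mitochondrial, ribosomal protein and haemoglobin genes, a test against a log2 fold change of 1, and leaving out each library in turn. Where a group is left with 1 library, it is assumed to vary like the other groups. DESeq2 and limma-voom on only the compared groups, and list and set tests on only the compared groups, were added after the data had been seen.

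The pipeline was tested on simulated counts with the fitted spread of the libraries, with 100 genes changed 4-fold and 100 changed 16-fold. For hypoxia against normoxia, the fit of all 8 libraries recovered 2 and 14 of them with 6 false calls, the fit of the P12 libraries alone 0 and 14 with 0 false calls, and limma-voom 0 and 3 with 0 false calls. For E15 against E13, the fit of all 8 libraries recovered 0 and 12 with 0 false calls, the fit of the embryonic libraries alone 97 and 100 with 10, and limma-voom 76 and 100 with 74. A list of 20 genes raised 2-fold at the spread of the P12 libraries had a camera p of 0.000272, and 1 of 30 unchanged lists was called. Genes were drawn independently in these simulations, so they cannot show how camera behaves where the genes of a list are correlated.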

Results

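Gene expression was measured by RNA sequencing in 8 libraries of tdTomato-positive mouse brain cells that the labels call progenitor cells. tdTomato is a red fluorescent protein that marks cells for sorting. The libraries form 4 groups of 2: embryonic day 13 (E13), embryonic day 15 (E15), postnatal day 12 after rearing in normal air (P12 normoxia) and postnatal day 12 after chronic hypoxia (P12 hypoxia). Hypoxic pups breathed 10% oxygen for 8 days, from P3 to P11. Each library was made from 400 pg of total RNA. Counts in gene rows totalled 37619289 and 42322568 in the hypoxic libraries, 46023539 and 36252027 in the normoxic, 41114190 and 40610695 at E13, and 41521485 and 47084796 at E15. At least 10 counts were found for 12785 and 11695 genes in the hypoxic libraries and for 14129 and 16468 in the normoxic, against 17520 to 18318 in the embryonic. The 100 most abundant genes held 26.7% to 34.5% of the counts at P12 and 14.2% to 14.9% in the embryo. Replicates correlated across genes (log of CPM, edgeR's counts per mega-count of normalised library size, genes not being independent replicates) with r = 0.95 at E13 and at E15, 0.77 in normoxia and 0.70 in hypoxia. Hypoxic and normoxic libraries correlated with each other at 0.70 to 0.71, so the hypoxic replicates were no closer to each other than to the normoxic libraries. Replicate spread measured here is spread between libraries only, since no label says whether replicates came from separate animals, and p-values measure no other spread.

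Chronic hypoxia was compared with rearing in normal air at the same age, to ask how progenitors respond to neonatal injury. Synapse genes were lower after hypoxia as a group, with 19 of 22 fold changes negative and 4 called lower, a result lost with an estimated correlation (limma camera, adjusted p = 0.359). Stmn2, a microtubule regulator of growing axons, fell by 8.59 on the log2 scale (SE 0.57 from the fit of all 8 libraries, n = 2 libraries per group). G2/M genes were higher as a group, with 17 of 20 positive fold changes and a median log2 fold change of 1.5, and Nusap1, a mitotic spindle protein, rose by 1.88 (SE 0.34). Both this group and oligodendrocyte progenitor genes, 12 of 13 of them positive with a median log2 fold change of 2.02 and none passing alone, were lost with an estimated correlation (limma camera, adjusted p = 0.227 for each). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 602 of 19936 genes were called, 39 higher and 563 lower, and 3632 had an unadjusted p under 0.05, 943 higher and 2689 lower. Of the calls 6.5% were higher, against 34.4% in DESeq2 and 8.5% in DESeq2 on the 4 P12 libraries alone. edgeR on the 4 P12 libraries alone called 0 (1558 at an unadjusted p under 0.05), as did the fit without E13 replicate 1, E13 replicate 2, E15 replicate 1 or E15 replicate 2. limma-voom with sample weights called 0 (1699 unadjusted) and DESeq2 3981, DESeq2 on the 4 P12 libraries alone called 1363, of which 575 were among the 602, and the edgeR count was 3018 without hypoxic replicate 1, 1740 without hypoxic replicate 2, 922 without normoxic replicate 1 and 982 without normoxic replicate 2.

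The 8 largest falls by fitted fold change were of genes with no count in either hypoxic library. For these only a lower bound can be given, taken at 3 counts per library, and the bounds do not rank them against genes that were counted. Camkv, a synaptic vesicle-associated pseudokinase, stood at 230 and 337 CPM in the normoxic libraries and was at least 2680-fold lower in hypoxia. Stra6, a receptor that takes up vitamin A, was at least 1070-fold lower, and Ckmt1, a mitochondrial creatine kinase, at least 649-fold lower. Rem2, a small GTPase that acts on calcium channels, was at least 536-fold lower, Syndig1l at least 470-fold and Sult4a1, a brain sulfotransferase, at least 400-fold. Penk, the precursor of enkephalin, had 39.8 and 43.9 CPM in normoxia and was at least 395-fold lower, and Spata2l was at least 385-fold lower. Among the rises, Ctf1, the cytokine cardiotrophin, had 21.9 and 74.6 CPM in hypoxia and no count in normoxia, at least 500-fold higher. Dmrtb1, a DM-domain transcription factor, was at least 241-fold higher on the same terms. Kif20b, a mitotic kinesin, rose with a ratio of 323 (95% counting interval 89.3 to 2660), Zfp677 with a ratio of 1700 (581 to 8230) and Ticam1, an adaptor of Toll-like receptors, with a ratio of 1050 (358 to 5080). Their log2 fold changes without 1 library ran from 8.099 to 8.423, from 9.706 to 14.957 and from 9.01 to 14.275 in that order. Gorab, a Golgi protein, rose by 8.26 on the log2 scale (SE 1.02), Med26, a Mediator subunit, by 8.13 (SE 1.12) and Wdr46 by 8.12 (SE 0.73). These 16 genes had edgeR Benjamini-Hochberg adjusted p-values from 0.0195 to 0.0476. Bounds and intervals cover counting error only.

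Of 36 gene lists 6 passed in this comparison, 4 higher and 2 lower in hypoxia, and 0 passed with an estimated correlation. The G2/M list had the smallest adjusted camera p, 6.48e-06. Its adjusted p over 12 alternatives ran from 4.8e-07 to 0.227, the last with an estimated correlation. Of its 20 measured genes 1 was called higher over all genes and 3 when adjusted over the list alone. In 11 of them both hypoxic libraries lay above both normoxic ones. With no difference between the groups this would hold for 16.7% of genes, but genes of a list are not independent, and the share over all tested genes is not given. Kif11, a mitotic kinesin, had a log2 fold change of 1.92 (SE 0.37) and Plk1, a mitotic kinase, of 1.80 (SE 0.41), and neither passed over all genes. Mki67, the proliferation marker, had 182 and 125 CPM in hypoxia and 95.9 and 79.0 in normoxia, with a log2 fold change of 0.81 (SE 0.37). The list of G1/S and DNA replication genes did not pass (limma camera, adjusted p = 0.582), with 14 of 25 members positive and 1 called lower.

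Oligodendrocyte lineage genes were higher in hypoxia as groups. The oligodendrocyte progenitor list passed with an adjusted camera p of 5.78e-04, with 0 of 13 members called over all genes and 0 adjusted over the list alone. It was lost with an estimated correlation (adjusted p = 0.227 with an estimated correlation), the highest of 12 alternatives, whose lowest adjusted p was 1.18e-05. Olig2, a transcription factor of the lineage, had 119 and 163 CPM in hypoxia and 44.9 and 24.8 in normoxia. Gpr17, a receptor of committed precursors, had 350 and 724 against 205 and 113, and Neu4, a sialidase, had 47.7 and 65.6 against 0.127 and 2.67. Maturing oligodendrocyte genes also passed (limma camera, adjusted p = 0.02; 8 of 10 positive, 0 called, 0 adjusted over the list alone), with adjusted p = 0.385 with an estimated correlation, the highest of 12 alternatives, and 0.000248 as the lowest. Mbp, myelin basic protein, had 216 and 170 CPM in hypoxia and 17.3 and 58.8 in normoxia. The maturing list missed the threshold without hypoxic replicate 1 (0.159), hypoxic replicate 2 (0.123) or normoxic replicate 1 (0.29).

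Of 4 neuron lists 2 passed in hypoxia, both lower. Synapse genes passed with an adjusted camera p of 1.96e-04, with 19 of 22 fold changes negative, a median log2 fold change of -2.31, 4 called lower and 8 when adjusted over the list alone. The adjusted p was 0.0668 without hypoxic replicate 1, and adjusted p = 0.359 with an estimated correlation was the highest of 12 alternatives, the lowest being 1.06e-05. Snap25, a SNARE protein of vesicle release, fell by 7.52 on the log2 scale (SE 0.67). Syp, synaptophysin, was lower by a ratio of 1080 (194 to 42800), with 1 count over both hypoxic libraries, and Grin2a, a glutamate receptor subunit, by a ratio of 7920 (2190 to 65400). Their log2 fold changes without 1 library ran from -12.807 to -8.813 for Syp and from -16.665 to -11.729 for Grin2a. Grin1, the obligatory subunit of the same receptor, fell by 8.58 on the log2 scale (SE 1.45). General neuron genes passed (limma camera, adjusted p = 0.0398; 9 of 16 negative, 3 called lower, 6 adjusted over the list alone), and Ina, a neuronal intermediate filament, fell by 8.01 (SE 0.58). Over 12 alternatives their adjusted p ran from 0.000238 to 0.752, being 0.592 with an estimated correlation, 0.752 without hypoxic replicate 1, 0.176 without normoxic replicate 1, 0.0817 without E13 replicate 1 and 0.0791 without E13 replicate 2. Axon guidance genes did not pass (limma camera, adjusted p = 0.22), nor did glutamatergic neuron genes (0.956), of which 13 of 20 were positive and 6 negative with a median log2 fold change of 0.31. Of the latter 2 were called lower: Bcl11b, a transcription factor of deep-layer and striatal neurons, by a ratio of 1970 (544 to 16200), and Mef2c, which fell by 9.56 on the log2 scale (SE 1.22). The log2 fold change without 1 library ran from -14.579 to -9.7 for Bcl11b and from -10.617 to -8.913 for Mef2c. Beside these groups, genes with at least 10 counts were fewer in both hypoxic libraries than in either normoxic library.

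Regulators named by the study's question were measured directly. Mettl14, a subunit of the m6A RNA methyltransferase (GRCm38 chromosome 3, 123368297 to 123386108), had 86.3 and 140 CPM in hypoxia and 30.1 and 28.2 in normoxia. Its log2 fold change of 1.95 (SE 0.45) did not pass (edgeR adjusted p = 0.0983). Over 20 alternatives the adjusted p of Mettl14 ran from 1.01e-05 in DESeq2 to 0.478 in edgeR on the P12 libraries alone, and it was 0.0131 in edgeR without hypoxic replicate 1. Axin2, a target of Wnt signalling (chromosome 11, 108920349 to 108950783), had 118 and 100 CPM against 4.64 and 15.8. The Axin2 log2 fold change of 3.42 (SE 0.80) did not pass either (edgeR adjusted p = 0.0986), with a range from 1.28e-06 in DESeq2 to 0.386 in limma-voom and 0.046 in edgeR without normoxic replicate 2. Ctnnb1, which encodes beta-catenin (chromosome 9, 120929216 to 120960507), had 344 and 219 CPM against 214 and 161, a log2 fold change of 0.59 (SE 0.28). The m6A list passed as a group (limma camera, adjusted p = 0.0378; 15 of 20 positive, 0 called, 1 adjusted over the list alone), with adjusted p = 0.504 with an estimated correlation, the highest of 12 alternatives, and 0.00851 as the lowest. It missed the threshold without hypoxic replicate 2 (0.401) or normoxic replicate 2 (0.163). Per-library means of the m6A list overlapped between the groups, at 5.96 and 6.45 in hypoxia and 6.23 and 5.94 in normoxia. Mettl3, the catalytic partner of Mettl14, had 17.8 and 0.111 CPM in hypoxia and 27.4 and 2.54 in normoxia. Ythdf3, a reader of the mark, had a log2 fold change of 1.72 (SE 0.33) that did not pass. Wnt target genes did not pass as a list (limma camera, adjusted p = 0.083; 0 of 17 called, 2 higher adjusted over the list alone), and Lef1 had at most 1 count in any P12 library.

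Lists of progenitor identity genes did not pass between the P12 groups. For single genes, the main fit recovered 2 of 100 simulated 4-fold changes. A simulated list of 20 independent genes raised 2-fold had a camera p of 0.000272, but lists of correlated genes were not simulated. Eomes, the transcription factor of intermediate progenitors, had 12.9 and 77.7 CPM in hypoxia and 22.7 and 63.3 in normoxia. Neurog2, which promotes glutamatergic fate, had 33.1 and 12.1 against 0.603 and 44.8, and Pax6, of radial glia, had 150 and 406 against 318 and 130. Neither the radial glia list (limma camera, adjusted p = 0.582) nor the intermediate progenitor list (0.718) passed, with 1 of 18 and 0 of 15 members called. Genes induced by hypoxia-inducible factor did not pass as a list (limma camera, adjusted p = 0.339), and the 2 called members were lower: Ankrd37, at least 60.8-fold, and Ero1l, an oxidoreductase of the endoplasmic reticulum, which fell by 5.84 on the log2 scale (SE 1.01). Vegfa, the angiogenic factor, had 0.605 and 1.03 CPM in hypoxia and 0.984 and 4.27 in normoxia, and Slc2a1, a glucose transporter, had 44.5 and 49.4 CPM in hypoxia, with a log2 fold change of 0.44 (SE 0.65). Notch pathway genes did not pass as a list either (limma camera, adjusted p = 0.624), with 2 of 18 called lower: Nrarp, a feedback inhibitor, fell by 6.26 (SE 1.05), and Numb, an inhibitor of Notch, by 4.05 (SE 0.72). Per the labels, hypoxia ended at P11, before the P12 stage of the libraries.

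**Figure D1:**
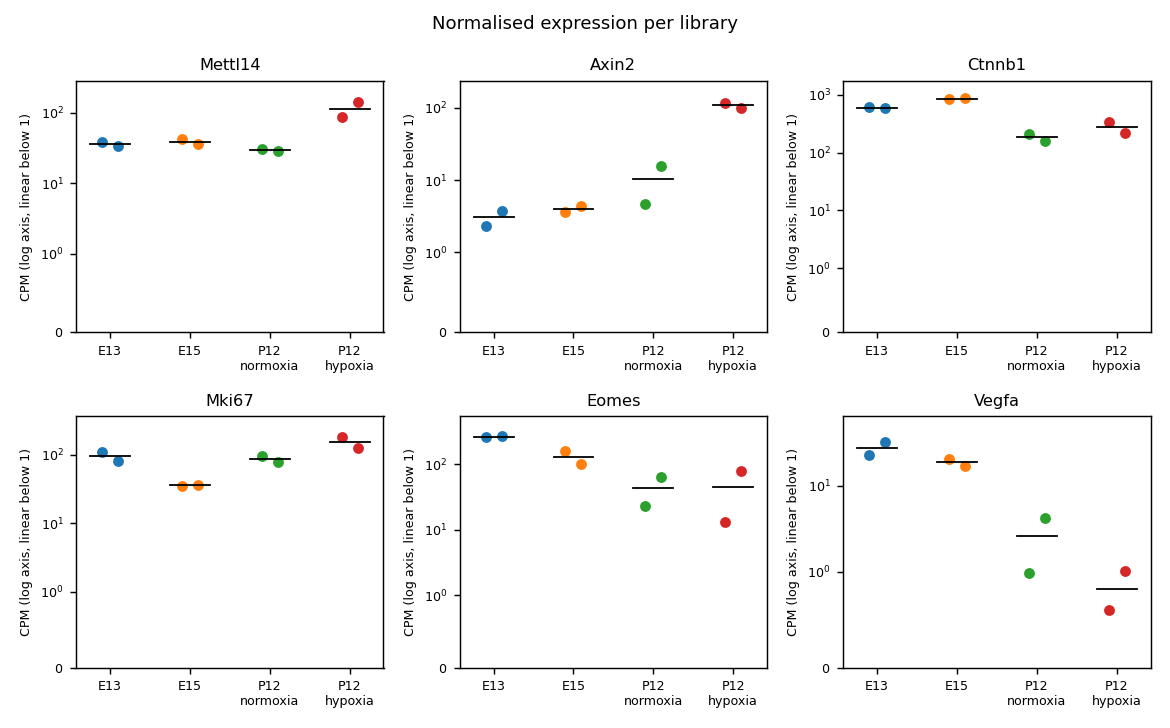
Normalised expression of 6 genes per library (y axis, CPM, logarithmic above 1 and linear below), with points for the 2 libraries of each group (x axis) and bars for the group mean. Mettl14 and Axin2 lie higher in both hypoxic libraries than in the other 6, while Eomes overlaps between the P12 groups, from 12.9 to 77.7 CPM in hypoxia and from 22.7 to 63.3 in normoxia.

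A further comparison asked whether hypoxic P12 cells lay nearer to embryonic cells, using genes that separated P12 from the embryo. Of the 500 genes most clearly higher in the embryo, 301 had a negative and 136 a positive log2 fold change after hypoxia, with a median of -1.13 (-0.75 with absent genes at their bound), and 167 fell while 7 rose. In each fit without 1 library the 500 genes were chosen anew, so the values of these fits are not of 1 fixed set. The median was -5.45 without hypoxic replicate 1, -4.86 without hypoxic replicate 2, -0.41 without normoxic replicate 1 and -0.42 without normoxic replicate 2. The members called were 105 lower and 61 higher without normoxic replicate 2, 365 and 29 without hypoxic replicate 1, 300 and 22 without hypoxic replicate 2, and 0 without any 1 embryonic library. The set was lower in hypoxia by camera (p = 3.09e-13), and over 15 alternatives p ran from 1.81e-39 to 0.041, with p = 0.0188 with an estimated correlation. The 500 genes most clearly higher at P12 were slightly higher in hypoxia (camera p = 0.000662, median log2 fold change 0.13), with 0 members called higher and 3 lower, and p = 0.323 with an estimated correlation. That call was also lost without hypoxic replicate 2 (0.0514 by camera) and without normoxic replicate 2 (0.478), the lowest of 15 alternatives being 5e-11. The 200 genes ranked highest for E13 and the 200 for E15, none of them called between these stages, did not move as sets (camera p-values of 0.899 for those higher at E13 and 0.692 for those higher at E15). These sets were chosen on the same libraries, and the hypoxic libraries had fewer genes with at least 10 counts. A gene absent from the hypoxic libraries enters the set higher in the embryo more easily through that absence, and is then lower in hypoxia. The choice of the set therefore favours its direction. These p-values cannot decide whether hypoxic cells lay nearer to or further from the embryo.

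Within the embryo, E15 cells were compared with E13 cells to describe how progenitors change with age. All 20 measured G2/M genes were lower in both E15 libraries than in both E13 libraries, with a median log2 fold change of -1.55. With no difference between the stages this would hold for 16.7% of genes, but genes of a list are not independent. The share over all tested genes is not given, and the m6A list, which did not pass, had 6 of 20 genes higher and 7 lower on the same terms. Nusap1 had 107 and 115 CPM at E13 and 38.6 and 38.1 at E15, and Top2a, the topoisomerase of dividing cells, had 310 and 416 against 121 and 128. Tcf7l2, a transcription factor of Wnt signalling, was higher at E15, with 20.5 and 37.5 CPM against 0.894 and 1.35. Luzp2 had 88.1 and 98.2 CPM at E15 against 8.21 and 6.36, and Bcan, the matrix proteoglycan brevican, had 17.2 and 16.4 against 1.57 and 2.78. Embryonic globin RNA was abundant at E13 alone among the groups, with Hbb-y at 2550 and 8810 CPM and at 0.423 and 0.129 at E15. No gene passed edgeR's quasi-likelihood test in the fit of all 8 libraries (0 called, 690 at an unadjusted p under 0.05, 254 higher and 436 lower). The same test on the 4 embryonic libraries alone called 229, 90 higher and 139 lower, while DESeq2 called 373 and limma-voom 935 in all 8 libraries. The common dispersion was 0.968 in the fit of all 8 libraries and 0.172 in the embryonic libraries alone, and simulated 4-fold changes were recovered for 0 of 100 genes in the first fit and for 97 of 100 in the second.

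Of 36 lists 13 passed between the stages, 12 lower at E15 and 1 higher. G2/M genes were lower at E15 (limma camera, adjusted p = 8.39e-14), with 0 members called over all genes and 2 adjusted over the list alone. Over 12 alternatives the adjusted p ran from 5.88e-42 to 0.0771, the last being the adjusted p with an estimated correlation. G1/S genes were lower as well (limma camera, adjusted p = 0.00456; 23 of 25 negative, 0 called, 0 adjusted over the list alone), with adjusted p = 0.237 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, had 253 and 281 CPM at E13 and 99.1 and 86.2 at E15. That list missed the threshold without E13 replicate 2 (0.0856) or E15 replicate 2 (0.0812). Early progenitor timing genes were lower (limma camera, adjusted p = 0.000315; 10 of 11 negative, 0 called, 0 adjusted over the list alone), with adjusted p = 0.236 with an estimated correlation. Lin28b, an inhibitor of let-7 maturation, had 3.79 and 10.8 CPM at E13 and no count at E15, at least 144-fold lower. Intermediate progenitor genes were lower (limma camera, adjusted p = 0.0182; 10 of 15 negative, 0 called, 2 adjusted over the list alone), with adjusted p = 0.236 with an estimated correlation, and not without normoxic replicate 1 (0.0549), E13 replicate 2 (0.146) or E15 replicate 2 (0.173). Gadd45g had 299 and 322 CPM at E13 and 84.8 and 61.2 at E15, and Btg2, an antiproliferative gene, had 239 and 317 against 119 and 88.5. Synapse genes were the list higher at E15 (limma camera, adjusted p = 0.0377; 15 of 22 positive, 0 called, 0 adjusted over the list alone), with adjusted p = 0.43 with an estimated correlation and up to 0.536 over 12 alternatives, among them 0.356 without E13 replicate 2, 0.266 without E15 replicate 2 and 0.105 without either normoxic library. Gria2, a glutamate receptor subunit, had 214 and 276 CPM at E15 and 108 and 91.5 at E13.

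Genes of other cell types were also compared between the embryonic stages. Erythroid genes were lower at E15 in 10 of 10 members (limma camera, adjusted p = 5.11e-30; 0 called, 9 adjusted over the list alone), with adjusted p = 0.223 with an estimated correlation. Haemoglobin genes held 0.69% and 2.379% of the counts at E13, 0.003% and 0.011% at E15 and 0% at P12. Hba-x, an embryonic globin, had 301 and 1080 CPM at E13 and 0.476 and 0.305 at E15, and Car2, a carbonic anhydrase abundant in red cells, had 7.87 and 36.2 against 0.493 and 0.402. Plpp3, a lipid phosphatase of glial cells, had 126 and 94.1 CPM at E13 and 35.3 and 30.3 at E15, and Pantr1, a noncoding RNA beside Pou3f3, had 65.4 and 61.1 at E13 and 267 and 240 at E15. The remaining 7 lists that passed were all lower at E15, with adjusted camera p-values from 2.27e-05 to 0.0437: ependymal, Notch, p53 target, oligodendrocyte progenitor, mural, astrocyte and unfolded protein response genes. Expression of the glial lists was low at both stages. The oligodendrocyte progenitor list had means of 0.45 and 0.52 at E13 and 0.23 and 0.23 at E15, and the astrocyte list 1.54 and 1.77 against 1.35 and 1.48. Without E13 replicate 2 all 7 missed the threshold, with adjusted p-values of 0.0836, 0.182, 0.146, 0.0743, 0.977, 0.287 and 0.287 in that order. The mean of the mural list was 0.43 and 1.97 at E13 and that of the ependymal list 0.74 and 1.47. Oligodendrocyte progenitor genes missed it without any 1 of the 8 libraries (0.0552 to 0.225), and except for ependymal genes the others missed it without E15 replicate 2 as well (0.0696 to 0.1). None of the 13 lists passed with an estimated correlation, which gave the highest adjusted p over 12 alternatives for the erythroid, G2/M, G1/S, timing and intermediate progenitor lists. Of the 36 lists 3 passed without E13 replicate 2, 5 without E15 replicate 2, 6 without normoxic replicate 1 and 8 without normoxic replicate 2 or E15 replicate 1.

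Normoxic P12 cells were compared with the mean of E13 and E15 as the developmental reference for the hypoxia comparison. Genes of glia were far higher at P12: 14 of 15 astrocyte genes and 11 of 13 oligodendrocyte progenitor genes rose. Gfap, the astrocyte intermediate filament, had 1180 and 884 CPM at P12 and a single count over the 4 embryonic libraries, a ratio of 238000 (95% counting interval 42700 to 9400000). Glutamatergic neuron genes did not pass as a list (limma camera, adjusted p = 0.129), with 4 of 20 risen and 6 fallen. The falls included Neurod6, with 1450 to 1920 CPM in the embryo and at most 0.0652 at P12, and Slc17a7, a vesicular glutamate transporter, with no count at P12 and at least 1080-fold lower. Radial glia genes were higher rather than lower, with 12 of 18 risen, beside the rise of astrocyte and oligodendrocyte progenitor genes. Which cells carried these transcripts was not tested, so the rise does not show that radial glia were more abundant at P12. As lists, astrocyte, oligodendrocyte progenitor and radial glia genes were each lost with an estimated correlation (limma camera, adjusted p = 0.0552, 0.0552 and 0.0707). edgeR's quasi-likelihood test called 3541 of 19936 genes, 2408 higher and 1133 lower (68% higher, against 56.9% in DESeq2 and 78.7% in limma-voom). The count was 928 to 975 without any single embryonic library, 1747 without normoxic replicate 1, 5990 without hypoxic replicate 1 and 5831 without hypoxic replicate 2, and stage was confounded with other measures of the libraries, mitochondrial genes holding 0.31% and 0.40% of the counts in the normoxic P12 libraries and 1.25% to 1.38% in the embryonic ones.

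The largest rises at P12 by fitted fold change were mostly of genes with no count in the embryo. Rgs5, a regulator of G protein signalling also known from pericytes, had 2500 and 1910 CPM and was at least 42300-fold higher, and Bhlhe41, a circadian repressor, was at least 29400-fold higher. Hepacam, an adhesion protein of astrocytes, was at least 9400-fold higher, Thbs4, a matrix glycoprotein, at least 6590-fold, Grin2a at least 5360-fold and Emp2, a membrane protein, at least 4660-fold. Sdc4, a cell surface proteoglycan, rose by 16.95 on the log2 scale (SE 1.06). The largest falls by fitted fold change held adult globins and transcription factors of embryonic neurons. Hba-a1 was at least 13900-fold lower at P12 and Hba-a2 at least 7750-fold, and Nhlh2 was at least 1540-fold lower, Lhx9 at least 1250-fold, Prdm8 at least 918-fold and St18 at least 905-fold. Neurod6 was lower by a ratio of 36100 (12300 to 175000). Together with Gfap and Slc17a7, given above, these 16 genes had edgeR Benjamini-Hochberg adjusted p-values from 0.000324 to 0.0444.

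Of 36 lists 16 passed, 9 higher and 7 lower at P12, and 0 passed with an estimated correlation, which gave the highest adjusted p over 12 alternatives for each of the 16. The smallest p-values were of astrocyte, oligodendrocyte progenitor and immediate early genes. Astrocyte genes passed with an adjusted camera p of 1.55e-14 (15 higher adjusted over the list alone), with adjusted p = 0.0552 with an estimated correlation. Apoe, a lipid carrier secreted by astrocytes, rose by 9.49 on the log2 scale (SE 0.32) and Slc1a2, the main glutamate transporter, by 8.72 (SE 0.37). The oligodendrocyte progenitor list passed (limma camera, adjusted p = 2.74e-08; 12 adjusted over the list alone), also with adjusted p = 0.0552 with an estimated correlation, and Gpr17 was at least 3060-fold higher. Radial glia genes passed (limma camera, adjusted p = 6.89e-06; 12 adjusted over the list alone), with adjusted p = 0.0707 with an estimated correlation. Their called members included Notch2, which rose by 8.22 on the log2 scale (SE 0.41), and Ptprz1, Hes5 and Fabp7, which rose by 5.49 (SE 0.27), 6.50 (SE 0.52) and 2.78 (SE 0.21). GABAergic lineage genes passed (limma camera, adjusted p = 4.16e-05; 7 of 13 risen, 9 adjusted over the list alone), with adjusted p = 0.0778 with an estimated correlation. Gsx2, a transcription factor of the ventral germinal zone, was at least 2310-fold higher and Gad1, which makes GABA, at least 983-fold. FGF and EGF pathway genes passed as well (limma camera, adjusted p = 0.000176; 7 of 17 risen, 9 adjusted over the list alone), with adjusted p = 0.211 with an estimated correlation, and Spry2, a feedback inhibitor, rose by 11.28 (SE 0.32).

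Other lists described the same comparison. Intermediate progenitor genes were lower (limma camera, adjusted p = 0.031; 2 of 15 risen and 5 fallen, 3 and 6 adjusted over the list alone), with adjusted p = 0.186 with an estimated correlation, and not without normoxic replicate 1 (0.0668) or normoxic replicate 2 (0.177). Mfap4 fell by 11.92 on the log2 scale (SE 0.84) and Rasgef1b by 5.24 (SE 0.70), whereas Btg2 and Gadd45g, antiproliferative and stress-inducible genes, rose by 5.03 (SE 0.23) and 1.90 (SE 0.30). Synapse genes passed (limma camera, adjusted p = 0.00919; 8 of 22 risen, 9 adjusted over the list alone), with adjusted p = 0.256 with an estimated correlation and 0.0579 without normoxic replicate 1, and Grin2b rose by 11.21 (SE 0.67). General neuron genes did not pass (limma camera, adjusted p = 0.0862), with 5 of 16 fallen, among them Tubb3, a neuronal tubulin, by 3.61 (SE 0.47). Immediate early genes, which respond to cell dissociation as well as to signals, passed (limma camera, adjusted p = 6.92e-08; 13 of 18 risen, 15 adjusted over the list alone), with adjusted p = 0.168 with an estimated correlation. Fos rose by 4.15 (SE 0.26) and Junb by 8.08 (SE 0.61). Mitochondrially encoded genes were lower at P12 (limma camera, adjusted p = 0.000152; 6 of 13 fallen, 8 adjusted over the list alone), with adjusted p = 0.168 with an estimated correlation, and mt-Co2 fell by 3.48 (SE 0.20) and mt-Atp6 fell by 2.97 (SE 0.23). Endothelial genes were lower (limma camera, adjusted p = 0.00255; 5 of 10 fallen, 7 adjusted over the list alone), with adjusted p = 0.168 with an estimated correlation and 0.0562 without normoxic replicate 2, and Cldn5, a tight junction protein of vessels, was at least 16.8-fold lower. The Cldn5 call (edgeR adjusted p = 0.0398) was lost in 10 of 17 alternatives, with adjusted p-values from 0.0003 to 0.199, among them those without either normoxic library or without any 1 embryonic library. The other 6 lists that passed had adjusted camera p-values from 0.000673 to 0.0376, with ependymal and maturing oligodendrocyte genes higher and erythroid, ribosomal protein, axon guidance and G2/M genes lower. Maturing oligodendrocyte genes lost their call in 5 of 12 alternatives, G2/M genes in 3 and the others in 1 each, and 0 of 20 G2/M genes were called alone. Rps24, a ribosomal protein, had a log2 fold change of 5.50 (SE 0.14), against its list of 40, of which 4 fell. Its reads can be shared with pseudogenes, and a difference of preparation or read length between stages, with which stage may be confounded, was not tested. Of 30 Wnt pathway genes 4 rose and 3 fell (limma camera, adjusted p = 0.27). Tcf7l2 rose by 8.33 (SE 0.43) and Ctnnb1 fell by 1.94 (SE 0.27).

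Against the embryo, the hypoxic and normoxic P12 libraries were tested together, and the side with more calls depended on the setting. limma-voom called 2960 genes higher and 2210 lower, and edgeR with at least 5 CPM in 2 libraries 2652 and 2267. More calls were also higher with the replicate block and without any single embryonic library. DESeq2 called 4531 higher and 4754 lower, and in the remaining settings more were lower too. In the main fit, edgeR's quasi-likelihood test called 6022 of 19936 genes, 2817 higher and 3205 lower. The count ranged from 1754 to 1797 without any single embryonic library. DESeq2 called 9285.

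**Figure D2:**
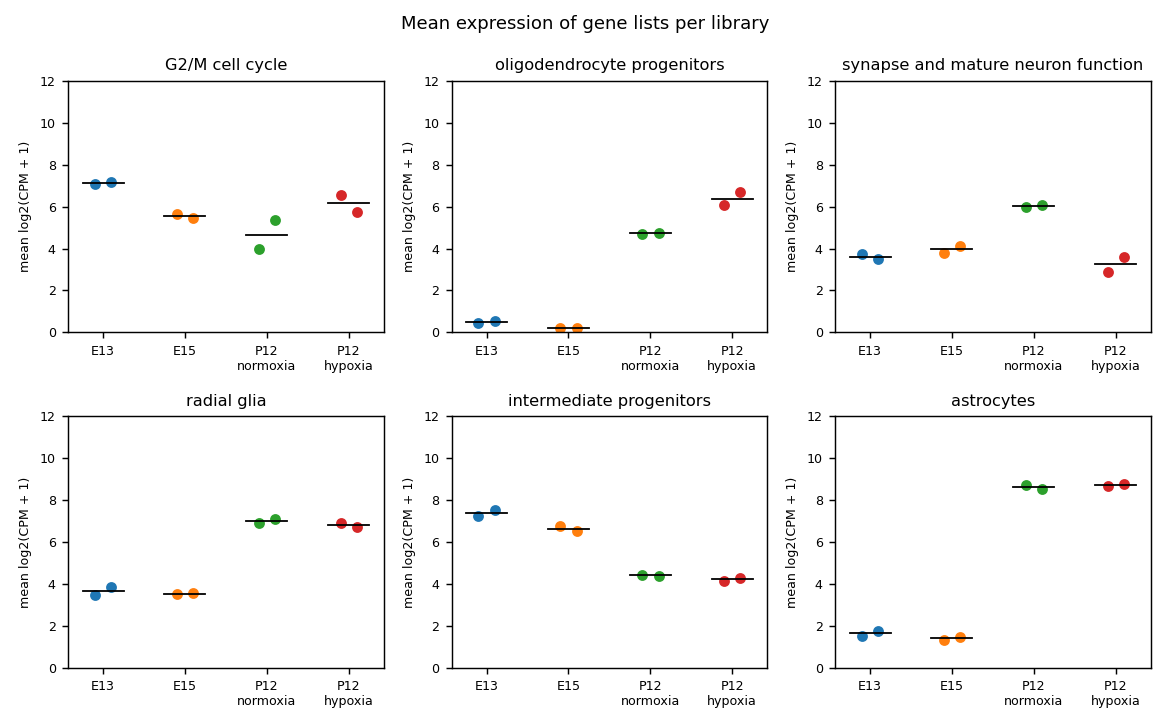
Mean expression of 6 gene lists per library (y axis, mean of log2(CPM + 1) over the measured genes of a list), with points for the 2 libraries of each group (x axis) and bars for the group mean. The G2/M list stands at 7.09 and 7.17 at E13, 5.65 and 5.47 at E15, 3.96 and 5.37 in P12 normoxia and 6.57 and 5.75 in P12 hypoxia, and the synapse list at 5.97 and 6.07 in P12 normoxia and 2.89 and 3.62 in P12 hypoxia.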

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

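The tests of spread, of a single low library, of cycling cells and of red blood cell RNA were chosen only after the result was seen, and the outcomes of the tests of transcript loss, striatal RNA and library splits were written before their values were computed.

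Entries of the deposited tables that name no gene, which no comparison used, held a mean of 0.262% of the counts in the hypoxic libraries, against 0.238% and 0.239% in the normoxic ones. No explanation was tested.

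The first pattern is the excess of lower genes in hypoxia, 563 of 602 calls. It was smaller in DESeq2, with 2611 of 3981 calls lower. Simulations with no difference and the spread of the P12 libraries gave at most 1 call in 20 runs, but their genes were drawn independently. Real splits that mixed hypoxic and normoxic libraries called 131 and 0. The common dispersion was 1.39 in the P12 libraries alone and 0.968 in the fit of all 8, so that fit understated their spread. edgeR on the P12 libraries alone called 0. How far the understated spread made the excess stays open. Independent loss of transcripts in each hypoxic library stays open too: genes absent from both hypoxic and present in both normoxic libraries were 209 against 59.6 expected, a ratio of 3.51, lower than the 4.05 to 13.63 of the other 5 arrangements and outside both outcomes written beforehand. A candidate explanation is RNA of striatal projection neurons in the normoxic libraries, since 20 of 20 markers of these neurons were lower in hypoxia with a median log2 fold change of -4.70. Hypoxia itself stays open as a biological cause, and none of these can be told apart with 2 libraries per group, nor was the sort, which should remove unlabelled neurons, testable without reporter counts.

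The second pattern is the higher G2/M list in hypoxia. Whether a single low normoxic library was the only source stays open. The list kept an adjusted camera p of 0.000434 without normoxic replicate 1. The adjusted p also stayed under 0.05 without each other P12 library and in the fit of the P12 libraries alone. These p-values cannot decide the question, since camera with the preset correlation of 0.01 takes the genes of a list as nearly independent. Without normoxic replicate 1 a single normoxic library remains. Its list mean of 5.37 lay below both hypoxic means, but nearer to the lower one than the hypoxic means lay to each other. The list was lost with an estimated correlation (limma camera, adjusted p = 0.227), and normoxic replicate 1 carried part of the difference, the list means being 6.57 and 5.75 in hypoxia and 3.96 and 5.37 in normoxia. More cycling cells of any kind, for which G1/S genes would rise as well, stays open, as the G1/S list had a camera p of 0.332 with 14 of 25 members positive. A response of the progenitors to hypoxia stays open and was not tested otherwise.

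The third pattern is the erythroid list, higher at E13. Red blood cell RNA in the E13 libraries is a candidate source, since all 10 erythroid genes were higher in E13 replicate 2 than in replicate 1, by a median ratio of 3.41, and their log2 ratios had an SD of only 0.51. Blood in the embryo at E13, a biological difference of age, brings the same RNA, and the sort for tdTomato would be expected to remove red cells.

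The difference of all P12 from all embryonic libraries was set against other splits of the 8 libraries in a fit of 2 groups. The real split called 4962 genes and the highest of the others 0, so 1 of 35 splits gave as many. Each other split put P12 and embryonic libraries on both sides, which widens the spread within a side and leaves few calls beforehand. The splits therefore cannot decide on chance. The 4 P12 libraries allow only 3 splits, too few for a share under 0.05: hypoxia against normoxia called 602, hypoxic replicate 1 with normoxic replicate 2 against the rest 131, and hypoxic replicate 1 with normoxic replicate 1 against the rest 0.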

How the results depend on the processing

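The 602 calls of hypoxia against normoxia became 3981 in DESeq2, 0 in limma-voom with sample quality weights, 295 with no low-count filter and 0 in edgeR with only the groups compared, and stayed between 459 and 742 under 5 other settings. Chosen after the data had been seen, DESeq2 with only the groups compared called 1363 and limma-voom with only the groups compared 0. Leaving out 1 library gave 0 to 3018. E15 against E13 went from 0 calls to 373 in DESeq2, 935 in limma-voom and 229 with only the groups compared, and, chosen after the data had been seen, to 2288 in DESeq2 and 450 in limma-voom on those groups, with 0 without any 1 library. The embryonic libraries vary less than the P12 ones, with a common dispersion of 0.172 alone against 1.39 for the P12 libraries alone and 0.968 together. Normoxic P12 against embryonic went from 3541 to 7252 in DESeq2 and 6731 with only the groups compared, and ranged from 928 to 5990 without 1 library. Both P12 groups against embryonic went from 6022 to 9285 in DESeq2 and ranged from 1754 to 8068 without 1 library. Upper-quartile scaling moved the median log2 fold change of all genes from 0 to -0.104 in hypoxia, from -0.04 to -0.244 in normoxic P12 against embryonic and from -0.391 to -0.652 for both P12 groups, which relative log expression moved to -0.286.

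A block for the replicate number, which names no known pair, left 1 call in hypoxia, 0 in E15 against E13, 1705 in normoxic P12 against embryonic and 3924 for both P12 groups, and the cause was not tested. Under the block Eomes had a log2 fold change of -0.047 and Neurog2 of 0.398 in hypoxia.

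Lists past the threshold were 0 with an estimated correlation in all 3 comparisons. In hypoxia fry passed 7 lists, 2 higher and 5 lower, where camera passed 4 higher and 2 lower, and it lost the m6A (0.128) and maturing oligodendrocyte (0.0924) lists. fry passed 0 for E15 against E13 and 26 for normoxic P12 against embryonic, where camera passed 13 and 16. Without 1 library the lists numbered 4 to 7 in hypoxia, 3 to 12 for E15 against E13 and 14 to 17 for normoxic P12. No list changed direction, and none of the 35 calls held under every alternative. The gene sets that follow were chosen anew in each fit without 1 library. Genes higher in embryonic than in P12 cells stayed lower in hypoxia in every setting (camera p-values of 1.81e-39 to 0.041 without 1 library), while those higher at P12 had 0.323 with an estimated correlation and 5e-11 to 0.478 without 1 library. The set higher at E13 changed direction without cell cycle list members (0.846), without other cell type list members (0.725) and, chosen after the data had been seen, with only the 4 P12 libraries (0.213), and also without normoxic replicate 1 (0.718), E13 replicate 1 (0.464) or 2 (0.0608), or E15 replicate 1 (0.846) or 2 (0.712), its p running from 0.0608 to 0.951 without 1 library. The set higher at E15 changed direction without normoxic replicate 1 (0.736) or E13 replicate 1 (0.829) or 2 (0.731), its p running from 0.138 to 0.829.

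Of 29 genes called in hypoxia and reported, none kept its call under every alternative and none changed direction, while 32 of 41 called in normoxic P12 against embryonic kept theirs. The other 9 were Cldn5, lost in 10 of 17 alternatives, Prdm8, lost in 9 of 18, Gadd45g, lost in 4, Hba-a2, lost in 3, and Grin2a, Hba-a1, Neurod6, Rasgef1b and Tubb3, lost in 1 each. Directions that changed were of uncalled genes. The log2 fold change of Eomes was -0.09 with upper-quartile factors, -0.361 in limma-voom and -0.353 in limma-voom with only the groups compared, and -1.671 to 0.994 without 1 library. That of Neurog2 was 0.215 with relative log expression factors, 0.215 in DESeq2, 2.019 in limma-voom, 0.027 with no low-count filter, 0.117 in DESeq2 and 1.998 in limma-voom with only the groups compared, and -0.815 to 5.22 without 1 library. Without 1 library Mettl3 ran from -6.955 to 1.94, Pax6 from -0.607 to 1.349 and Slc2a1 from -0.174 to 1.765.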

Other observations

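The tests of striatal neuron markers were chosen after the largest falls in hypoxia had been seen, among them Penk, Syndig1l and Camkv, and before the values of the markers themselves were looked at.

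RNA known from striatal projection neurons was abundant in the normoxic P12 libraries. Arpp21, a phosphoprotein of the striatum, had 917 and 941 CPM in normoxia and 31.3 and 214 in hypoxia. Foxp1, a transcription factor of striatal neurons, had 186 and 607 against 42.6 and 0.333, and Adora2a, the adenosine receptor of enkephalin-bearing neurons, had 212 and 264 against 40.2 and 0. Drd2, a dopamine receptor of the same neurons, had 49.4 and 37.7 CPM in normoxia and no count in hypoxia, whereas Drd1, the receptor of the other striatal output pathway, had 0.794 and 2.90 in normoxia. Of 20 such markers 15 had at least 10 CPM in both normoxic libraries, and 6 had at least 10 CPM in an embryonic group. As a list they were lower in hypoxia (camera p = 5.65e-08, and p = 0.00459 with an estimated correlation), with 0 members called alone.

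A hypothesis from these values is that part of the hypoxia comparison may reflect striatal neurons, or cells of a striatal lineage, that were present in the normoxic libraries and scarce in the hypoxic ones. The median log2 fold change of the 20 markers, -4.70, fits this. A list of 5 cortical projection neuron markers, run beside it, had a median of 0 (2 positive, 2 negative, a camera p of 0.866), but 4 of the 5 had at most 0.349 CPM in every P12 library, so it does not limit the hypothesis to striatal neurons. The synapse list was lower in hypoxia too, and the glutamatergic list was not. The planned GABAergic lineage list did not pass in hypoxia (limma camera, adjusted p = 0.479), with 9 of 13 members negative, 4 positive and 0 called. Its median log2 fold change was -2.16, and -0.5 with absent genes at their bound. Whether the neurons of both output pathways took part stays open, Drd1 being low and Tac1, of the same pathway, having 2.57 and 29.5 CPM in normoxia. The tdTomato sort would be expected to remove unlabelled cells, and whether hypoxia or the dissection of these libraries made the difference was not tested.

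Counts of sex-linked genes differed within groups. Xist had 1460 counts in hypoxic replicate 1 and 0 in hypoxic replicate 2, where the Y-linked Ddx3y had 1 and 5468, whereas each of the other 6 libraries had at least 657 counts of Xist and at least 1042 of Ddx3y. Libraries with both could hold cells of animals of both sexes, while the hypoxic replicates look like 1 sex each. The Y-linked Kdm5d, with 4 counts and 1 count in the normoxic libraries, goes against that reading there. Leaving out any 1 P12 library raised the calls from 602, to 3018 and 1740 without a hypoxic and to 922 and 982 without a normoxic one, so the rise was not particular to the hypoxic libraries.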
